A study of Homo sapiens with 20 samples.

How the data were processed

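Gene expression was measured by RNA sequencing of MCF7 cells in 20 libraries of 10 groups with 2 libraries each. The deposited files hold, per the file headers, an estimated count of reads (not normalised) and a TPM value (transcript abundance scaled to a fixed total) for each of 201758 transcripts, with an annotated and an effective transcript length. The authors made the estimated counts and the TPM values with Salmon 0.10.2 on GRCh37, as the submitters' processing notes state, and neither the annotation release, the Salmon options nor the library strand is given. Effective lengths exceeded the annotated length for part of the transcripts, so the deposited TPM carry a bias correction, which the counts do not.

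Transcripts were assigned to genes by their Ensembl identifiers in GENCODE v29, which is on GRCh38 and served for names and transcript types alone, so no coordinates are given. This matched 197330 transcripts (97.8%), 56176 genes and 99.8% of the counts of each library. Estimated counts were summed per gene and rounded. Estimated counts divide reads between close paralogs (HSPA1A and HSPA1B, the MT1 genes, AKR1C1, AKR1C2 and AKR1C3, TRIM16 and TRIM16L, the histones) and, with the strand not given, between overlapping genes, so the values of such genes are uncertain.

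Counts were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr on the groups, which left 17834 genes, TMM scaling and 1 quasi-likelihood fit of all 20 libraries with a term per group (10 residual degrees of freedom). Each of 16 comparisons had its own F test, with p-values adjusted by Benjamini and Hochberg within the comparison and a threshold of 0.05. The 6 comparisons of an oxidant with vehicle of the same time came first, then menadione against TBOOH at each of 3 times, vehicle against the time before, and the change of each response between times. The standard error is the log2 fold change divided by the square root of F. Log2 CPM for figures, components and levels used a prior count of 2. With 2 libraries a group, no comparison could be set against regroupings of its samples.

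The comparisons, the tests, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Genes were named by rule, from those past the threshold with a symbol, a mean log2 CPM of at least 1 and both libraries of a group above both of the other. The rule took the 6 largest rises and 6 largest falls of each comparison with vehicle, the 5 and 5 of each comparison of the oxidants, and the 4 and 4 of each other comparison. From each list it took up to 4 members past the threshold by adjusted p, and the most abundant member not past it. Genes named outside the rule are said to have been chosen after their values were seen. A gene is named by its symbol.

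The 30 gene lists (651 entries, 8 without a match) were tested with limma 3.58.1 by camera with a preset correlation of 0.01 between genes, which asks whether a list ranks above or below the other genes. They were tested again with the correlation estimated from the data, and by fry. Their p-values were adjusted over the 30 lists of a comparison. Of 270 pairs of list and comparison, 16 had a median, mean and camera direction that differed in sign, 0 of them past camera's threshold. Lists share genes with each other, so their results are not independent, and the 4 leukocyte, 7 mesenchymal and 6 basal markers served as markers of other cell types.

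The samples were checked for batches. The replicate number separated all 20 libraries on the first principal component (33.6% of the variance). The median ratio of effective to annotated length was 0.958 to 0.997 in replicate 1 libraries and 0.747 to 0.781 in replicate 2 libraries. Over the 45 pairs of groups, differences between replicates 1 and 2 correlated across genes at 0.468 to 0.606 (median 0.553). The biological coefficient of variation was 0.235, and 0.085 with the replicate number in the model. The numbers thus mark a split, of a cause not known, that pairs the libraries, and a fit with the replicate number added, called the replicate block, is given beside the counts and list calls it changes.

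The procedure was tested on simulated data with the gene means, spread and replicate difference of these libraries, with changes put into menadione at 1 h. Of 50 genes changed by 2-fold, edgeR called 28, and 38 with the replicate block, of 50 changed by 4-fold 44 and 48, and over all simulated changes it made 2 and 6 false calls. In a simulated comparison with no changed gene, menadione with vehicle at 24 h, it made 0 calls, and 3 with the replicate block. A simulated list of 25 genes changed by 1.5-fold was found by camera (adjusted p = 8.95e-35, and adjusted p = 2.07e-06 with an estimated correlation) and by fry (adjusted p = 1.54e-06), with 0 unchanged lists past the threshold in any of the 3. Apart from the replicate difference, genes were drawn independently in these data. The simulation thus cannot show how often camera with its preset correlation falsely calls lists of correlated genes. The correlation of the oxidants was set against 20 simulations with no effect and shared vehicle libraries. A shared effect with a variance of 0.1 put into such data came back as 0.0895.

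The alternatives were RLE and total count scaling, no filter and a mean CPM of at least 5, robust dispersion, effective lengths as an offset, limma on log2(TPM + 1), DESeq2 1.42.0, a fit of the compared groups alone, the replicate block, and each library left out in turn. In the last, a group with 1 library left was assumed to vary like the others. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Nothing was left out of the deposited libraries.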

Results

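RNA was sequenced from MCF7 cells, a human breast cancer line that expresses the estrogen receptor, in 20 libraries. Untreated cells at 0 h gave 2 libraries, and vehicle (0.1% ethanol), menadione (10 µM) and tert-butyl hydroperoxide (TBOOH, 80 µM) each gave 2 libraries at 1, 8 and 24 h. Menadione is a quinone that cycles between reduced and oxidised forms in cells, and TBOOH is an organic peroxide. The estimated counts totalled 22815726 to 30133377 in replicate 1 libraries and 21666005 to 25314961 in replicate 2 libraries, and 17834 genes were tested. Changes are log2 fold changes ± the standard error of the fit, from 2 libraries against 2, and levels are CPM (counts scaled to the library total) ± SD, n = 2. Each gene said to have risen or fallen passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Behind the count of a gene list, "list alone" marks the count adjusted over that list's genes alone, and "block" the count with the replicate number added to the fit (the replicate block), in the same direction unless stated. The p-values measure the spread between these libraries alone, since nothing states that the replicates were separate cultures. Without the block, that spread includes the split by replicate number (biological coefficient of variation 0.235, and 0.085 with the block). Standard errors from that fit thus tend to be wider, and a gene that did not pass may pass with the block.

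At 8 h, the comparison of menadione with vehicle asked which transcripts the quinone had changed, and CYP1A1 rose furthest under the rule for named genes. CYP1A1, a monooxygenase of foreign compounds, rose by 7.18 ± 0.83, from 3.47 ± 0.828 to 506 ± 48.7 CPM. HMOX1, which degrades heme, rose by 4.84 ± 0.88, and ALDH3A1, an aldehyde dehydrogenase, by 4.22 ± 0.19. SLC7A11, the cystine transporter subunit that supplies glutathione synthesis, rose by 4.21 ± 0.49, AKR1C1, an aldo-keto reductase, by 3.94 ± 0.48, and FOSL1, a subunit of the AP-1 transcription factor, by 3.44 ± 0.63. These 6 genes had adjusted p from 2.67e-07 to 0.0214. The falls were shallower, with AKAP5, a scaffold of protein kinase A, at -1.52 ± 0.29, ANKRD35 at -1.28 ± 0.24, LRP4, a receptor of the LDL receptor family, at -1.14 ± 0.24, and OVOL2, an epithelial transcription factor, at -1.07 ± 0.18. TEX14 fell by 1.03 ± 0.19 and the antisense transcript GPC1-AS1 fell by 1.05 ± 0.22, the latter uncertain because the strand of the libraries is not given.

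**Figure D1:**
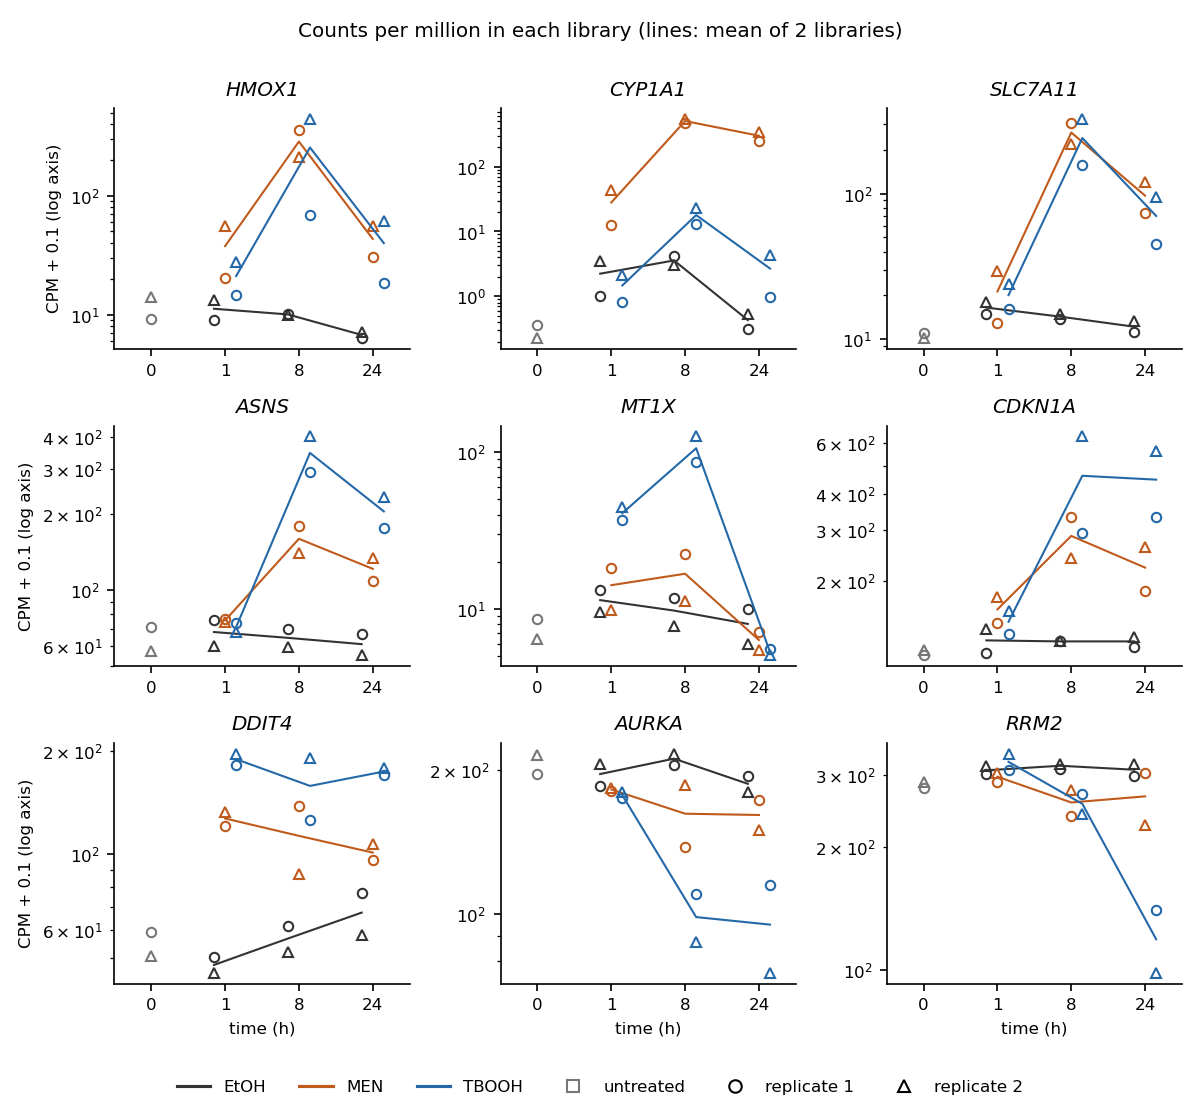
CPM (plus 0.1, log axis) of 9 genes in each of the 20 libraries, by treatment and time in hours, with lines through the mean of the 2 libraries of a group. CYP1A1 reached 300 ± 67.7 CPM under menadione at 24 h against 2.58 ± 2.39 CPM under TBOOH, while under TBOOH AURKA fell at 8 and 24 h and RRM2 fell at 24 h.

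Among the gene lists fixed in advance, NRF2 targets, the antioxidant genes of that transcription factor, had the highest count of rises with menadione at 8 h. Of the 35 measured, 21 rose and 14 did not pass the test, while 30 rose when adjusted over the list alone and 33 rose with the replicate block. AKR1C3 rose by 2.50 ± 0.22, the heme transporter SLC48A1 by 1.60 ± 0.17 and AKR1C2 by 2.37 ± 0.26, whereas ferritin heavy chain FTH1, at 1.03 ± 0.51, did not pass (adjusted p = 0.508, 0.00157 with the block). Counts of the AKR1C genes are uncertain, since their reads can be split between these close paralogs. The list ranked above the other genes by camera at an adjusted p = 4.47e-50, and at an adjusted p = 0.00902 with an estimated correlation. That call was lost with the replicate block (adjusted p = 0.075 with both the block and an estimated correlation). Of 23 peroxide and thiol redox enzymes, 2 rose (list alone 3, block 6), namely thioredoxin reductase TXNRD1 at 2.57 ± 0.34 and glutathione peroxidase GPX2 at 1.99 ± 0.30, and 21 did not pass. Of 14 iron handling genes, 2 rose, HMOX1 and SLC48A1, and 12 did not pass (list alone 4, block 6). The iron list ranked higher by camera (adjusted p = 0.00824; adjusted p = 0.108 with an estimated correlation), and the redox enzyme list did so only with the replicate block (adjusted p = 0.0618 without and 0.0205 with the block), a call lost at an adjusted p = 0.475 with both the block and an estimated correlation.

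Members of the ATF4 list, the targets of the integrated stress response, rose with menadione at 8 h. Of 23 members, 7 rose and 16 did not pass (list alone 19, block 18), with a median of 1.03. The amino acid transporter SLC7A5 rose by 2.37 ± 0.19, the secreted glycoprotein STC2 by 1.15 ± 0.14 and mitochondrial phosphoenolpyruvate carboxykinase PCK2 by 0.73 ± 0.11. Of 26 p53 targets, 2 rose (list alone 10, block 8), the stress cytokine GDF15 by 2.50 ± 0.40 and the growth arrest gene GADD45A by 2.49 ± 0.48, and 24 did not pass. Of 33 immediate early genes, 4 rose (list alone 8 higher and 1 lower, block 11 higher and 1 lower), among them the phosphatase DUSP5 at 1.78 ± 0.25, and 29 did not pass. ULK1, a kinase that starts autophagy, rose by 0.65 ± 0.10 and GABARAPL1, of the autophagosome, by 1.78 ± 0.35, the 2 of 21 autophagy and lysosome genes to do so (list alone 3, block 4). ADM, a vasodilator peptide, rose by 1.34 ± 0.29, 1 of 20 hypoxia targets (list alone 3, block 2), and the growth factor receptor IGF1R rose by 0.63 ± 0.13, 1 of 20 estrogen receptor targets (list alone 1, block 1 higher and 2 lower). The estrogen receptor list as a whole had a median of -0.32 and ranked lower by camera (adjusted p = 0.0211; adjusted p = 0.52 with an estimated correlation). The ATF4, p53 and immediate early lists ranked above the other genes by camera at adjusted p = 8.47e-24, 3.08e-11 and 1.79e-05. Their adjusted p = 0.102, 0.299 and 0.39 with an estimated correlation, so the ranking was not past the threshold there. The hypoxia list ranked higher at an adjusted p = 0.0437, against 0.0709 with the replicate block and an adjusted p = 0.56 with an estimated correlation.

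Cell-cycle lists had medians below 0 with menadione at 8 h, -0.41 over 25 mitosis genes (-0.539 and -0.31 within replicates 1 and 2) and -0.31 over 30 DNA replication genes. By edgeR, 0 of their members passed, with 7 and 2 lower at an unadjusted p under 0.05, 0 and 0 lower by DESeq2, and 2 and 2 with the replicate block. Both lists ranked below the other genes by camera (adjusted p = 1.71e-10 and 4.3e-08; adjusted p = 0.303 and 0.39 with an estimated correlation). Basal epithelial markers had a median of 0.46 and ranked higher (adjusted p = 0.0156; adjusted p = 0.39 with an estimated correlation). Of the 6 measured, 0 passed by edgeR, with 2 higher at an unadjusted p under 0.05, 1 by DESeq2 and 3 with the replicate block. The aminoacyl-tRNA synthetase, NF-kappaB, ribosome biogenesis, ribosomal protein and BCL2 lists also ranked higher, and the luminal, respiratory chain and interferon lists lower. Their adjusted p ran from 6.49e-08 to 0.0369, against an adjusted p = 0.198 to 0.733 with an estimated correlation. In all, 172 genes passed at 8 h, 152 higher and 20 lower. The total was 1133 (727 higher, 406 lower) with the replicate block and 490 by DESeq2, but 11 with effective lengths as an offset, 17 by limma on log2(TPM + 1) and 15 with the 4 libraries fitted alone. It was 43 without vehicle replicate 1, 21 without vehicle replicate 2, 56 without menadione replicate 1 and 110 without menadione replicate 2.

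At 24 h of menadione, the same question found CYP1A1 again far above vehicle. It rose by 9.80 ± 1.00, from 0.329 ± 0.157 to 300 ± 67.7 CPM. ALDH3A1 rose by 6.03 ± 0.21, AKR1C1 by 4.43 ± 0.49, CYP1B1, another monooxygenase, by 3.07 ± 0.42, SLC7A11 by 2.99 ± 0.47 and the retinol carrier receptor STRA6 by 2.83 ± 0.57, with adjusted p from 9.85e-09 to 0.0392. H19, an imprinted long noncoding RNA, fell by 1.95 ± 0.19, AOX1, an aldehyde oxidase, fell by 1.65 ± 0.27, SLC9A4, a sodium and proton exchanger, fell by 1.59 ± 0.31, and ASCL1, a transcription factor of neural cells, fell by 1.5 ± 0.25. CDH18, a cadherin, fell by 1.55 ± 0.33 and the ectonucleotidase NT5E fell by 1.54 ± 0.31. From 8 to 24 h, 69 of the rises were shared (0.99 by chance) and 2 of the falls (0.05 by chance), an overlap of comparisons with different vehicle libraries.

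NRF2 targets again had the highest count of rises at 24 h, with 16 of 35 higher (list alone 31, block 31) and 19 not past the test. Transketolase TKT rose by 0.91 ± 0.09, the quinone reductase NQO1 by 1.27 ± 0.13 and AKR1C3 by 2.03 ± 0.22. The list ranked above the other genes with an estimated correlation (adjusted p = 0.0213), a call lost with the replicate block (adjusted p = 0.119 with both the block and an estimated correlation). The same held for iron handling, where 2 of 14 rose (list alone 6, block 6), biliverdin reductase BLVRB by 0.76 ± 0.14 and SLC48A1 by 0.78 ± 0.17 (adjusted p = 0.023 with an estimated correlation, lost at an adjusted p = 0.119 with both the block and an estimated correlation). Ribosome biogenesis ranked higher too, with 1 of 25 higher (list alone 9, block 13), the ribosomal RNA methyltransferase NOP2 at 0.38 ± 0.08, and an adjusted p = 0.0311 with an estimated correlation, lost at an adjusted p = 0.171 with both the block and an estimated correlation. GPX2 rose by 2.66 ± 0.30 and TXNRD1 by 2.24 ± 0.33, 2 of 23 redox enzymes (list alone 3, block 6). SLC7A5 rose by 2.29 ± 0.19 and asparagine synthetase ASNS by 0.99 ± 0.21, with SLC7A11 the 3 ATF4 targets past the test (list alone 11, block 9). BMF, a promoter of cell death in the BCL2 family, rose by 1.94 ± 0.41, 1 of 14 (list alone 1 higher and 1 lower, block 2 higher and 1 lower), and GDF15 by 1.94 ± 0.39, 1 of 26 p53 targets (list alone 1, block 3). Of 16 NF-kappaB targets 1 rose (list alone 12, block 10), with a median of 0.83 (0.609 and 0.953 within replicates 1 and 2). The ATF4, p53, NF-kappaB and redox enzyme lists ranked higher by camera at adjusted p from 4.67e-11 to 0.00282, but their adjusted p = 0.12 to 0.367 with an estimated correlation.

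Falls at 24 h of menadione included members of the unfolded protein response, estrogen receptor and luminal lists. CALR, the calcium-binding chaperone calreticulin, fell by 0.73 ± 0.08 and HSP90B1 fell by 0.36 ± 0.07, 2 of 18 unfolded protein response genes (list alone 4, block 6). Cathepsin CTSD, at -0.50 ± 0.10, and the ubiquitin ligase SIAH2, at -0.40 ± 0.08, were the 2 of 20 estrogen receptor targets that fell (list alone 5 lower and 1 higher, block 7 lower and 0 higher). E-cadherin CDH1 fell by 0.43 ± 0.08, 1 of 16 luminal identity genes (list alone 2, block 6 lower and 2 higher), and the nuclear receptor NR4A3 fell by 1.46 ± 0.25, 1 of 33 immediate early genes (list alone 4 higher and 3 lower, block 4 higher and 6 lower). The unfolded protein, estrogen receptor and luminal lists ranked lower by camera at adjusted p from 5.3e-05 to 0.00208, with an adjusted p = 0.0854 to 0.302 with an estimated correlation. DNA replication, mitosis and cholesterol genes had medians of -0.26 (-0.066 and -0.522 within replicates 1 and 2), -0.27 (-0.167 and -0.371) and -0.22 (-0.212 and -0.247). By edgeR 0 of their members passed, with 3, 1 and 4 lower at an unadjusted p under 0.05, 0, 0 and 2 by DESeq2 and 1, 0 and 3 with the block. They ranked lower at adjusted p = 4.74e-07, 1.63e-05 and 4.74e-07, against an adjusted p = 0.205 to 0.399 with an estimated correlation. The aminoacyl-tRNA synthetase, proteasome and ribosomal protein lists ranked higher at adjusted p from 8.75e-07 to 0.000546, against an adjusted p = 0.367 to 0.421 with an estimated correlation. In all, 165 genes passed, 116 higher and 49 lower. The count was 1289 (722 higher, 567 lower) with the replicate block and 474 by DESeq2, but 24 with effective lengths as an offset, 36 by limma on log2(TPM + 1) and 2 with the 4 libraries fitted alone. It was 37 without vehicle replicate 1, 30 without vehicle replicate 2, 87 without menadione replicate 1 and 36 without menadione replicate 2.

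At 1 h, immediate early genes had a median of 0.47 with menadione, and no single gene passed the test. By edgeR 0 genes passed, with 264 at an unadjusted p under 0.05 and 7 by DESeq2. The replicate block gave 4 genes, all higher and named after their values were seen. These were CYP1A1 at 3.64 ± 0.47, TIPARP, an aryl hydrocarbon receptor target, at 1.61 ± 0.24, DDIT4, an inhibitor of mTOR signalling, at 1.42 ± 0.21, and the transcription factor MYC at 1.02 ± 0.10, with adjusted p from 0.00197 to 0.046 in that fit. A single simulated comparison with no changed gene gave 3 calls with the block, and vehicle at 24 h against 8 h gave 0. The count of 4 alone thus cannot tell these calls from false ones. Of 33 immediate early genes, 4 rose when adjusted over the list alone and 0 over all genes, with 8 higher at an unadjusted p under 0.05, 0 by DESeq2 and 1 with the block. That list ranked above the other genes by camera (adjusted p = 1.54e-22; adjusted p = 0.271 with an estimated correlation). ATF4 targets had a median of 0.28 (0.126 and 0.4 within replicates 1 and 2) and ranked higher too (adjusted p = 1.51e-10; adjusted p = 0.625 with an estimated correlation). Of the 23 measured, 0 passed by edgeR, with 5 higher at an unadjusted p under 0.05, 1 by DESeq2 and 1 with the replicate block. The NRF2, heat shock, p53, cholesterol, hypoxia, ribosomal protein and BCL2 lists also ranked higher, at adjusted p from 0.000197 to 0.0423, against an adjusted p = 0.625 to 0.917 with an estimated correlation. The interferon list, with a median of -0.13, ranked lower with the replicate block alone (adjusted p = 0.0522 without and 0.029 with it). Its medians within replicates 1 and 2 were -0.355 and 0.049, and the call was lost at an adjusted p = 0.823 with both the block and an estimated correlation. The count was 2 without menadione replicate 1 and 0 without each of the other 3 libraries of the comparison.

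TBOOH at 1 h asked for the earliest response to the peroxide, and DDIT4 rose by 1.99 ± 0.23 (adjusted p = 0.0165), from 47.5 ± 3.46 to 189 ± 9.89 CPM, the 1 gene past the test. Hypoxia targets, the genes of the HIF transcription factors, had a median of 0.57, but 0.305 and 0.873 within replicates 1 and 2. Of the 20 measured, 10 rose when adjusted over the list alone and 0 over all genes, with 11 higher at an unadjusted p under 0.05, 6 by DESeq2 and 5 with the replicate block. That list ranked above the other genes by camera (adjusted p = 7.01e-34) and with an estimated correlation (adjusted p = 0.0118). The latter call was lost with the replicate block (adjusted p = 0.0781 with both the block and an estimated correlation). Of 5 metal response genes, 2 rose when adjusted over the list alone and 0 over all genes by edgeR, with 2 higher at an unadjusted p under 0.05, 1 by DESeq2 and 2 with the block. Their median was 1.06, but 0.674 and 1.48 within replicates 1 and 2 (camera adjusted p = 2.56e-07; adjusted p = 0.277 with an estimated correlation). Members past the test with the replicate block, named after their values were seen, were the hypoxia targets ADM at 1.58 ± 0.23, PFKFB3, a regulator of glycolysis, at 1.41 ± 0.21, VEGFA, an angiogenic factor, at 1.25 ± 0.21, and KDM3A, a histone demethylase, at 1.09 ± 0.17. The zinc exporter SLC30A1 and metallothionein MT1X stood at 1.29 ± 0.18 and 1.88 ± 0.30 in that fit. Of 23 ATF4 targets 1 rose, DDIT4 (list alone 2, block 1). Their median was 0.28 (0.15 and 0.339 within replicates 1 and 2), and the list ranked higher (adjusted p = 6.61e-08; adjusted p = 0.789 with an estimated correlation). Immediate early and histone lists also ranked higher and mitosis genes lower, at adjusted p from 0.0266 to 0.0324, against an adjusted p = 0.789 to 0.922 with an estimated correlation. Proteasome subunits ranked lower with the replicate block alone (adjusted p = 0.0765 without and 0.0167 with it). Their median was -0.04 (-0.005 and -0.064 within replicates 1 and 2), and the call was lost at an adjusted p = 0.951 with both the block and an estimated correlation. The count was 22, all higher, with the replicate block and 23 by DESeq2, but 0 with effective lengths as an offset, by limma on log2(TPM + 1) and with the 4 libraries fitted alone, which gave 164, 206 and 253 at an unadjusted p under 0.05. It was 6 without TBOOH replicate 1 and 0 without each of the other 3 libraries.

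At 8 h of TBOOH, HMOX1 and a pair of metallothioneins stood far above vehicle, in the comparison that asked what the peroxide had changed by then. HMOX1 rose by 4.68 ± 0.87, from 9.94 ± 0.243 to 254 ± 263 CPM, with the TBOOH libraries far apart at 68.4 (replicate 1) and 440 CPM (replicate 2). The metallothioneins MT1F and MT1X, which bind zinc and copper, rose by 4.61 ± 0.55 and 3.46 ± 0.41, with counts uncertain between these paralogs. BEST1, a chloride channel, rose by 4.53 ± 0.57, SLC7A11 by 4.08 ± 0.49 and ADM2, a peptide of the adrenomedullin family, by 3.52 ± 0.43, and the 6 genes had adjusted p from 0.00161 to 0.00981. RASSF5, a Ras effector, fell by 2.48 ± 0.42, PLEKHS1 fell by 2.17 ± 0.62, the galactosyltransferase B3GALT5 fell by 2.15 ± 0.50, VASH2, a tubulin carboxypeptidase, fell by 2.0 ± 0.44, the kinase NRK fell by 1.89 ± 0.39 and MPP2 fell by 1.84 ± 0.34. The TBOOH replicate 2 library at 8 h stood apart, with 3.76% of its counts from mitochondrial rRNA against 1.38 to 2.45% in the other 19. The share at 8 h was above vehicle in replicate 1 of TBOOH too, at 2.45 against 1.49%, with vehicle replicate 2 at 1.63%. Under menadione at 8 h it was 2.25 and 2.27% in replicates 1 and 2, also above vehicle.

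ATF4 targets and aminoacyl-tRNA synthetases rose at 8 h of TBOOH. Of 23 ATF4 targets 19 rose, 1 fell and 3 did not pass (list alone 21 higher and 1 lower, block 21 higher and 1 lower). Their median was 1.11 within replicate 1 and 1.97 within replicate 2. ASNS rose by 2.42 ± 0.21, SLC7A5 by 2.31 ± 0.19, PCK2 by 1.80 ± 0.12 and PHGDH, which opens serine synthesis, by 1.48 ± 0.13. All 12 aminoacyl-tRNA synthetases measured rose (list alone 12, block 12), CARS1 by 1.22 ± 0.13, YARS1 by 1.18 ± 0.16 and MARS1 by 1.00 ± 0.12. Of 18 unfolded protein response genes 3 rose (list alone 3, block 6 higher and 1 lower), HERPUD1 by 1.02 ± 0.21 and the chaperone HSPA5 by 0.74 ± 0.17, and 15 did not pass. The 3 lists ranked above the other genes by camera at adjusted p = 1.79e-24, 1.02e-15 and 0.0312, the last 0.0624 with the replicate block. None held, at an adjusted p = 0.175, 0.175 and 0.348 with an estimated correlation.

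Members of the NRF2, metal and p53 lists rose as well at 8 h of TBOOH. Of 35 NRF2 targets 17 rose and 18 did not pass (list alone 20, block 26), with the stress-induced gene OSGIN1 at 2.17 ± 0.34 and TXNRD1 at 1.90 ± 0.33. TRIM16L rose by 1.62 ± 0.26, with reads uncertain between it and its parent gene. Of 5 metal response genes 3 rose (list alone 4, block 4 higher and 1 lower), MT2A by 2.52 ± 0.46. The zinc exporter SLC30A1, at -0.72 ± 0.42, did not pass (adjusted p = 0.334), but was lower with the block (adjusted p = 0.0167). Of 26 p53 targets 15 rose and 11 did not pass (list alone 20, block 21), with the cell-cycle inhibitor CDKN1A at 1.90 ± 0.33, the DNA damage sensor DDB2 at 1.02 ± 0.16 and FDXR at 1.42 ± 0.23. Of 14 BCL2 family genes 4 rose (list alone 4, block 4 higher and 1 lower), with the promoters of cell death BBC3 at 1.5 ± 0.34, PMAIP1 at 1.26 ± 0.29 and BAX at 0.77 ± 0.18. VEGFA rose by 2.01 ± 0.29 and EGLN3, a prolyl hydroxylase, fell by 1.03 ± 0.22 among 20 hypoxia targets, of which 6 rose and 1 fell (list alone 7 higher and 1 lower, block 9 higher and 1 lower). MAP1LC3B, an autophagosome protein, rose by 1.79 ± 0.32 and ULK1 by 0.90 ± 0.10, in 5 of 21 autophagy genes (list alone 6, block 7 higher and 1 lower).

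The NRF2, metal, p53 and hypoxia lists ranked above the other genes by camera at 8 h of TBOOH, at adjusted p from 3.75e-15 to 0.0127. Each lost that call, with an adjusted p = 0.175 to 0.561 with an estimated correlation. Iron handling had 3 genes higher and 1 lower of 14 (list alone 3 higher and 1 lower, block 5 higher and 2 lower), with BLVRB at 0.70 ± 0.14 and ACO1, an iron-regulated aconitase, at -0.55 ± 0.10. Its camera adjusted p was 0.0585 without and 0.0352 with the replicate block. That call was lost at an adjusted p = 0.315 with both the block and an estimated correlation. GPX2 rose by 1.36 ± 0.29, with TXNRD1 the 2 of 23 redox enzymes to rise (list alone 2, block 3 higher and 2 lower). MALAT1, a nuclear long noncoding RNA, rose by 0.65 ± 0.15, 1 of 8 nuclear and structural noncoding RNAs (list alone 1, block 4), with a camera adjusted p of 0.0804 without and 0.0379 with the replicate block, and an adjusted p = 0.315 with both the block and an estimated correlation. NFKB2 rose by 0.61 ± 0.16, 1 of 16 NF-kappaB targets (list alone 1, block 3 higher and 1 lower). IGF1R, at 0.58 ± 0.13, and SIAH2, at 0.29 ± 0.08, were the 2 of 20 estrogen receptor targets that rose (list alone 2, block 2 higher and 2 lower), with a list median of -0.16 (-0.135 and -0.243 within replicates 1 and 2; camera adjusted p = 0.248).

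Mitosis genes fell together at 8 h of TBOOH, 21 of 25 past the test (list alone 25, block 25) with a median of -0.97. That median was -0.75 within replicate 1 and -1.21 within replicate 2, whose TBOOH library was the 1 rich in mitochondrial rRNA. The kinesin KIF20A fell by 1.82 ± 0.29, the centromere motor CENPE fell by 1.44 ± 0.25, the checkpoint kinase BUB1 fell by 1.26 ± 0.21 and the spindle kinase AURKA fell by 1.09 ± 0.18. Of 30 DNA replication genes 5 fell and 25 did not pass (list alone 16, block 20), with the epigenetic regulator UHRF1 at -1.19 ± 0.26. Of 24 cholesterol genes 6 fell (list alone 15, block 18), with the sterol sensor partner INSIG1 at -0.92 ± 0.13 and DHCR24 at -0.73 ± 0.18. The estrogen receptor gene ESR1 fell by 1.01 ± 0.20 and AGR2, a disulfide isomerase, fell by 0.90 ± 0.24, 2 of 16 luminal genes (list alone 3, block 10). Of 23 heat shock genes 4 fell and 1 rose (list alone 6 lower and 2 higher, block 11 lower and 2 higher), the chaperones HSPA8 at -0.89 ± 0.13 and HSPA1A at -1.02 ± 0.15, the latter uncertain against its paralog HSPA1B. Of 16 interferon genes 2 fell, HERC5 at -0.99 ± 0.26 and IFIH1 at -0.71 ± 0.20, and IRF7 rose by 0.57 ± 0.14 (list alone 5 lower and 1 higher, block 6 lower and 1 higher). The mitosis, replication, cholesterol, luminal and heat shock lists ranked lower by camera at adjusted p from 2.65e-20 to 0.0341, and their adjusted p = 0.175 to 0.596 with an estimated correlation.

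Ribosomal proteins ranked higher at 8 h of TBOOH (adjusted p = 0.00248; adjusted p = 0.683 with an estimated correlation). In all, 1494 genes passed at 8 h of TBOOH, 681 higher and 813 lower. The count was 4698 (2148 higher, 2550 lower) with the replicate block, but 15 with effective lengths as an offset, 31 by limma on log2(TPM + 1) and 0 with the 4 libraries fitted alone, where edgeR gave 2245 genes at an unadjusted p under 0.05 and DESeq2 on all libraries gave 2137. It was 344 without vehicle replicate 1, 10 without vehicle replicate 2, 2763 without TBOOH replicate 1 and 66 without TBOOH replicate 2.

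**Figure D2:**
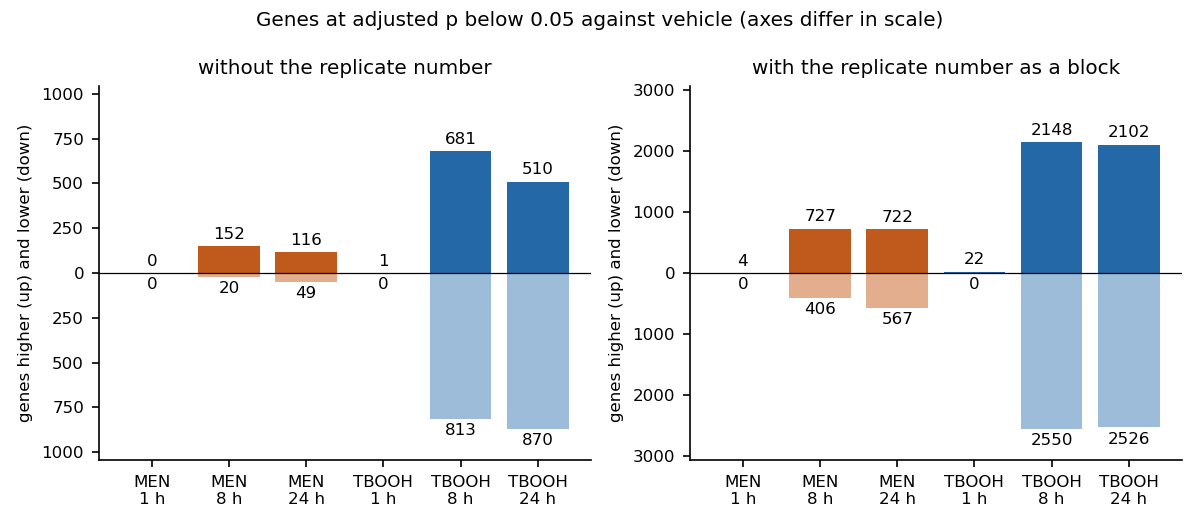
Number of genes higher and lower past the test (adjusted p under 0.05) for each comparison, as bars from 0, with and without the replicate number as a block. TBOOH against vehicle reached 1494 genes at 8 h and 1380 at 24 h, against 172 and 165 for menadione, and each of these counts was larger with the block. Each oxidant was used at a single dose, so compound and strength of exposure cannot be told apart.

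At 24 h of TBOOH, DNA replication genes fell as a group, in the comparison that asked what the peroxide had changed after a day. Of the 30 measured 29 fell (list alone 30, block 30), with a median of -1.05 (-0.842 and -1.35 within replicates 1 and 2). The ribonucleotide reductase subunit RRM2 fell by 1.37 ± 0.16, the replicative helicase subunit MCM5 fell by 1.16 ± 0.15, the licensing factor CDT1 fell by 0.90 ± 0.14 and MCM10 fell by 1.26 ± 0.20. Of 25 mitosis genes 20 fell and 5 did not pass (list alone 25, block 25), with medians of -0.589 and -1.28 within replicates 1 and 2, and with the scaffold ANLN at -1.01 ± 0.18 and AURKA at -0.97 ± 0.18. Both lists ranked below the other genes by camera (adjusted p = 1.16e-27 and 1.91e-19), with an adjusted p = 0.171 for each with an estimated correlation. The largest falls were those of AOX1 at -2.82 ± 0.29, NELL2 at -2.26 ± 0.55, the noncoding RNA NRAD1 at -2.25 ± 0.51, CNTNAP2, a neurexin relative, at -2.23 ± 0.32, CDCA7, a cell-cycle gene, at -2.12 ± 0.51 and NRGN at -2.12 ± 0.32, under the rule for named genes.

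Among the rises at 24 h of TBOOH, BEST1 rose by 4.17 ± 0.57, NIBAN1, a stress-induced gene, by 3.08 ± 0.70, AKR1C1 by 2.70 ± 0.47, ALDH3A1 by 2.62 ± 0.19, SLC7A11 by 2.53 ± 0.47 and the kinase DCLK1 by 2.46 ± 0.47, with adjusted p from 8.84e-05 to 0.0206. Of 26 p53 targets 18 rose and 8 did not pass (list alone 25, block 24), with TP53INP1 at 1.78 ± 0.27, SPATA18 at 1.70 ± 0.25 and SESN1 at 0.87 ± 0.15. Of 35 NRF2 targets 11 rose (list alone 18, block 22), with the export pump ABCC3 at 2.02 ± 0.28 and TKT at 0.59 ± 0.09. Of 23 ATF4 targets 11 rose and 1 fell (list alone 18 higher and 1 lower, block 17 higher and 1 lower), with ASNS at 1.74 ± 0.21 and PHGDH at 1.21 ± 0.13. Of 12 aminoacyl-tRNA synthetases 6 rose (list alone 11, block 11), WARS1 by 1.12 ± 0.27. Iron handling had 3 of 14 higher (list alone 9 higher and 2 lower, block 7 higher and 1 lower), BLVRB by 0.82 ± 0.14 and the ferrireductase STEAP3 by 0.65 ± 0.13. Autophagy and lysosome genes had 3 of 21 higher (list alone 7, block 10), ULK1 by 0.80 ± 0.10 and cathepsin CTSL by 0.74 ± 0.14. These 6 lists ranked above the other genes by camera at adjusted p from 2.55e-19 to 0.00447, and all lost that call at an adjusted p = 0.171 to 0.209 with an estimated correlation.

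Further lists had from 2 to 7 members past the test at 24 h of TBOOH. Cytosolic ribosomal proteins had 2 of 45 higher, RPL4 by 0.45 ± 0.09 and RPL26 by 0.35 ± 0.10 (list alone 1, block 31). Ribosome biogenesis had 5 of 25 lower (list alone 6, block 8), nucleolin NCL at -0.44 ± 0.12 and NOP58, of ribosomal RNA processing, at -0.45 ± 0.09. Of 24 cholesterol genes 7 fell (list alone 16, block 16), ACAT2 at -1.13 ± 0.19 and EBP at -0.85 ± 0.19. Of 18 unfolded protein response genes 4 fell and 1 rose (list alone 6 lower and 4 higher, block 8 lower and 3 higher), CALR at -0.82 ± 0.08 and HSP90B1 at -0.53 ± 0.07. Of 23 heat shock genes 2 fell (list alone 4 lower and 1 higher, block 14 lower and 1 higher), HSPE1 at -0.37 ± 0.08. The ribosomal protein list ranked higher and the ribosome biogenesis, cholesterol and heat shock lists lower by camera, at adjusted p from 6.01e-09 to 0.00434, against an adjusted p = 0.171 to 0.416 with an estimated correlation. AGR2 at -1.07 ± 0.24 and ESR1 at -0.74 ± 0.20 were the 2 of 16 luminal genes that fell (list alone 2 lower and 1 higher, block 7 lower and 1 higher), with a camera adjusted p of 0.0855 without and 0.0394 with the replicate block, and an adjusted p = 0.456 with both the block and an estimated correlation. The respiratory chain genes SDHA, at -0.35 ± 0.08, and NDUFB10, at -0.35 ± 0.09, fell, 2 of 35 (list alone 2, block 8). That list ranked lower by camera (adjusted p = 0.0216; adjusted p = 0.757 with an estimated correlation), and at 8 h with the replicate block alone (adjusted p = 0.0697 without and 0.00388 with it, lost at an adjusted p = 0.689 with both the block and an estimated correlation). IGFBP4 at -0.58 ± 0.14 and MYBL1 at -0.87 ± 0.22 were the 2 of 20 estrogen receptor targets that fell (list alone 2, block 7 lower and 1 higher), and the list ranked lower by camera (adjusted p = 0.0216; adjusted p = 0.487 with an estimated correlation).

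Markers of other cell types had medians of 0.72 (basal, 0.551 and 0.537 within replicates 1 and 2), -0.47 (leukocyte, -0.131 and -0.748) and -0.21 (mesenchymal, 0.057 and -0.215) at 24 h of TBOOH, with camera adjusted p = 0.144, 0.56 and 0.94. ACTA2, a smooth muscle actin, rose by 1.43 ± 0.28 at 8 h and 1.84 ± 0.29 at 24 h, 1 of 7 mesenchymal markers at each time (list alone 1 higher at 8 h and 1 higher and 1 lower at 24 h, block 1 higher and 0 lower at 8 h and 1 higher and 1 lower at 24 h). LAMC2, a laminin chain, rose by 0.75 ± 0.15 at 24 h, 1 of 6 basal markers (list alone 1, block 2). The NF-kappaB and noncoding RNA lists ranked higher and the proteasome list lower, at adjusted p from 0.0492 to 0.0496, against an adjusted p = 0.171 to 0.731 with an estimated correlation. Within replicates 1 and 2 the proteasome medians were -0.212 and 0.008, those of NF-kappaB 0.187 and 0.489, and those of noncoding RNAs 0.645 and 0.148. In all, 1380 genes passed at 24 h, 510 higher and 870 lower, and 191 rises (19.5 by chance) and 255 falls (39.7 by chance) were shared with 8 h. The count was 4628 (2102 higher, 2526 lower) with the replicate block, but 6 with effective lengths as an offset, 18 by limma on log2(TPM + 1) and 0 with the 4 libraries fitted alone, where edgeR gave 2106 genes at an unadjusted p under 0.05 and DESeq2 on all libraries gave 2038. It was 354 without vehicle replicate 1, 220 without vehicle replicate 2, 1634 without TBOOH replicate 1 and 25 without TBOOH replicate 2.

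**Figure D3:**
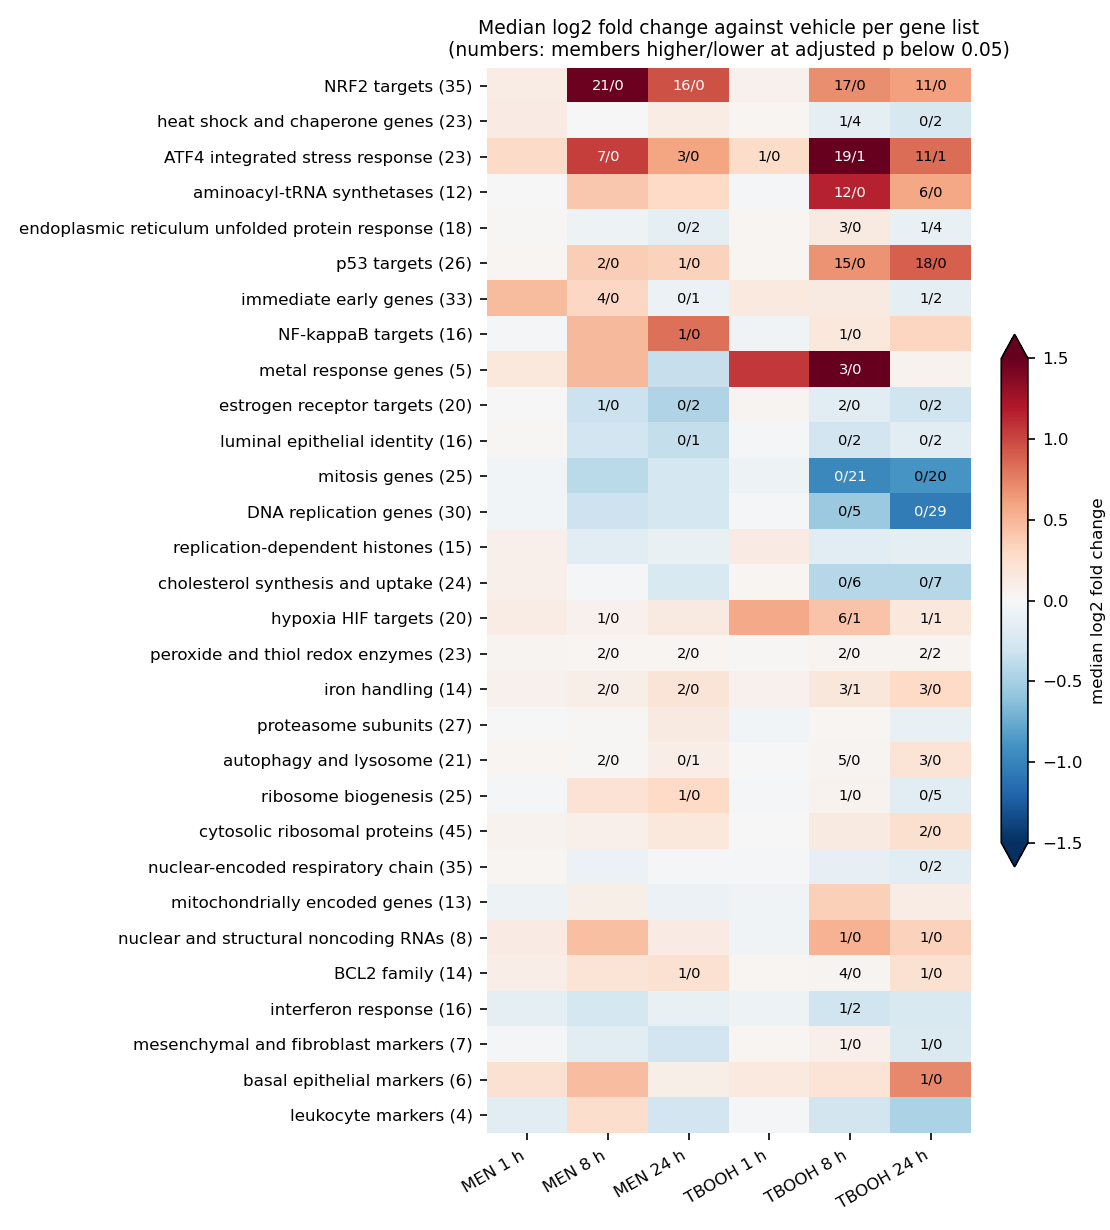
Median log2 fold change of the 30 gene lists (lines of the grid) in the 6 comparisons of an oxidant with vehicle (columns), as colour, with the numbers of members higher and lower past the test written in each square. NRF2 targets had medians of 1.47 and 0.96 under menadione at 8 and 24 h, and mitosis genes -0.97 and -0.88 under TBOOH.

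Some lists held 0 members past edgeR's test in all 6 comparisons of an oxidant with vehicle. For the 15 replication-dependent histones, the highest count in any of the 6 was 6 at an unadjusted p under 0.05, 0 by DESeq2 and 4 with the replicate block. For the 27 proteasome subunits these counts were 2, 2 and 3, and for the 13 mitochondrially encoded genes 0, 0 and 1. For the 4 leukocyte markers they were 2, 0 and 0. Adjusted over the list alone, each of these lists also had 0 members past the test. Across the 180 pairs of list and comparison, 79 were past the threshold of camera with its preset correlation, 5 with an estimated correlation, and 36 by fry, which asks whether a list's genes move on balance to 1 side.

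The direct comparison of the oxidants asked where their responses differ at the same time. At 8 h it found members of the NRF2 list higher under menadione and members of the metal and ATF4 lists higher under TBOOH. Each oxidant was used at a single dose, and nothing states that the doses were of equal strength. Differences between the compounds thus cannot be told apart from differences in strength of exposure. List medians differed between the replicates, at 0.934 and 0.191 within replicates 1 and 2 for NRF2, -0.189 and -0.998 for ATF4, -1.42 and -2.76 for metal response and 0.172 and 0.914 for mitosis genes. The TBOOH library of replicate 2 was the 1 rich in mitochondrial rRNA. CYP1A1 was higher under menadione by 4.83 ± 0.73, ALDH3A1 by 2.98 ± 0.18, AHRR, the repressor of the aryl hydrocarbon receptor, by 2.23 ± 0.22, the scaffold AKAP12 by 2.22 ± 0.39 and the nucleotide receptor P2RY6 by 2.14 ± 0.41. MT1F, at -4.25 ± 0.53, MT1X, at -2.67 ± 0.39, BEST1, at -2.41 ± 0.51, MT2A, at -2.03 ± 0.45, and transglutaminase TGM1, at -2.0 ± 0.38, were lower under menadione. NRF2 targets had 7 of 35 higher under menadione (list alone 14, block 17), AKR1C3 by 2.13 ± 0.22 and NQO1 by 0.65 ± 0.13. ATF4 targets had 6 of 23 lower (list alone 14 lower and 2 higher, block 13 lower and 0 higher), ASNS at -1.12 ± 0.20 and PCK2 at -1.07 ± 0.11, and aminoacyl-tRNA synthetases 4 of 12 (list alone 11, block 11). Mitosis genes had 2 of 25 higher (list alone 11, block 10), KIF20A by 1.32 ± 0.29, cholesterol genes 2 of 24 (list alone 12, block 13), INSIG1 by 0.78 ± 0.13, and heat shock genes 3 of 23 (list alone 5, block 7), HSPA8 by 0.78 ± 0.13. Metal response genes had 3 of 5 lower (list alone 4 lower and 1 higher, block 4 lower and 1 higher). These 7 lists passed camera at adjusted p from 7.25e-13 to 0.000612, and lost the call at an adjusted p = 0.293 to 0.46 with an estimated correlation. With the replicate block, NF-kappaB targets also ranked higher (adjusted p = 0.0752 without and 0.0298 with it) and cytosolic ribosomal proteins lower (0.107 without and 0.0111 with it). Both calls were lost at adjusted p = 0.641 and 0.772 with both the block and an estimated correlation. The immediate early, DNA replication and ribosome biogenesis lists ranked higher under menadione and the unfolded protein and p53 lists lower. Their adjusted p ran from 7.45e-05 to 0.00213, against an adjusted p = 0.293 to 0.762 with an estimated correlation. Among these lists the p53 median alone differed in sign between the replicates, at 0.102 and -0.634 within replicates 1 and 2. In all 298 genes differed, 204 higher and 94 lower under menadione. The count was 2194 (1291 higher, 903 lower) with the replicate block and 870 by DESeq2, but 0 with effective lengths as an offset (edgeR gave 804 at an unadjusted p under 0.05), 16 by limma on log2(TPM + 1) and 0 with the 4 libraries fitted alone (1154 at an unadjusted p under 0.05). It was 67 without menadione replicate 1, 35 without menadione replicate 2, 1059 without TBOOH replicate 1 and 33 without TBOOH replicate 2.

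**Figure D4:**
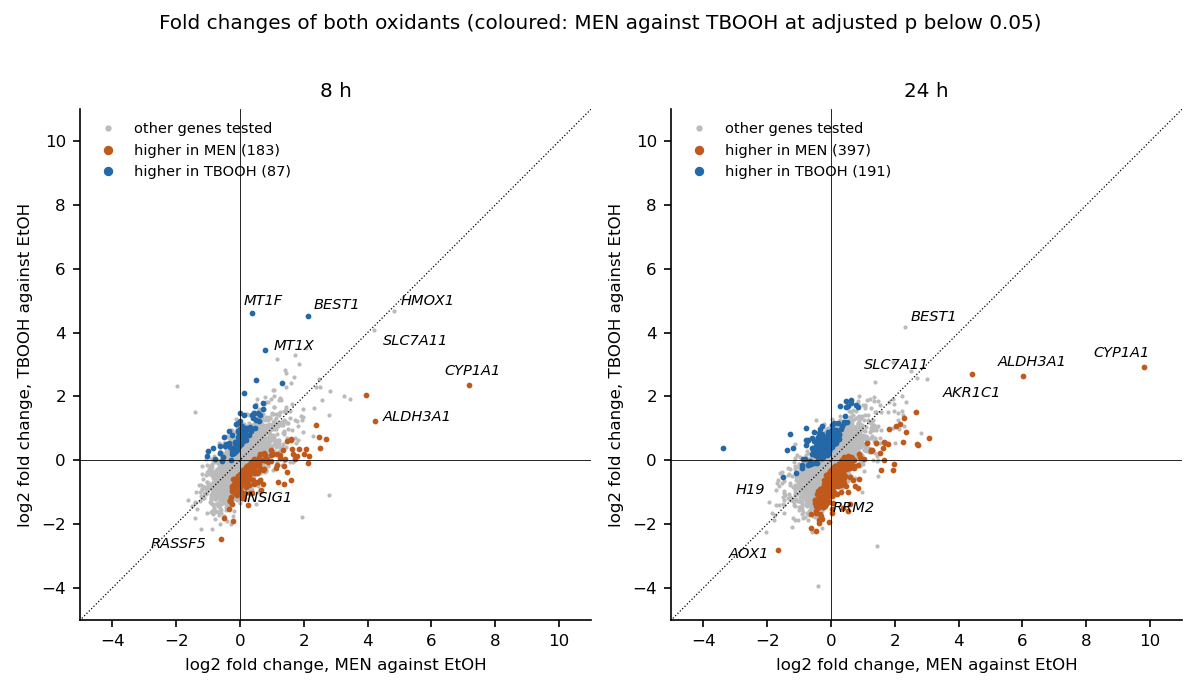
Log2 fold change of each gene under TBOOH (vertical axis) against that under menadione (horizontal axis), both against the same vehicle libraries, at 8 and 24 h, for 12744 genes with a mean log2 CPM of at least 1. Coloured points differed between the oxidants in the direct test, 183 higher under menadione and 87 higher under TBOOH at 8 h, and 397 and 191 at 24 h.

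At 24 h the oxidants differed in ribosome biogenesis and DNA replication genes as well. CYP1A1 was higher under menadione by 6.88 ± 0.82, ALDH3A1 by 3.40 ± 0.18, CYP1B1 by 2.37 ± 0.41, AHRR by 2.25 ± 0.22 and LMCD1, a transcriptional cofactor, by 2.23 ± 0.23. AC093668.2 stood lower under menadione at -3.75 ± 0.73, the glycine receptor subunit GLRA3 at -2.11 ± 0.19, the plexin PLXNA2 at -1.79 ± 0.20, annexin ANXA1 at -1.68 ± 0.36 and the peptidase KLK6 at -1.58 ± 0.36. Ribosome biogenesis had 11 of 25 higher (list alone 20, block 23), NOLC1 by 0.68 ± 0.09 and LYAR by 0.97 ± 0.17, and ranked higher by camera at an adjusted p = 6.19e-17, and at an adjusted p = 0.0461 with an estimated correlation. The latter call was lost at an adjusted p = 0.33 with both the block and an estimated correlation. DNA replication had 13 of 30 higher (list alone 27, block 28), RRM2 by 1.15 ± 0.16 and MCM5 by 0.98 ± 0.15, and mitosis 3 of 25 (list alone 22, block 17), AURKA by 0.76 ± 0.18. NRF2 targets had 5 of 35 higher (list alone 9, block 16), NQO1 by 0.95 ± 0.13, and p53 targets 4 of 26 lower (list alone 15, block 17), SPATA18 at -1.17 ± 0.25. These last 4 lists passed camera at adjusted p from 8.71e-21 to 6.82e-09, and each lost the call at an adjusted p = 0.337 with an estimated correlation. Proteasome subunits had 2 of 27 higher, PSMD12 by 0.40 ± 0.08 and PSMD11 by 0.38 ± 0.09 (list alone 5, block 16). Lower ranks appeared with the replicate block alone for cytosolic ribosomal proteins (adjusted p = 0.13 without and 0.00848 with it) and mitochondrially encoded genes (0.0555 without and 0.014 with it). Both calls were lost at adjusted p = 0.831 and 0.674 with both the block and an estimated correlation. Within replicates 1 and 2 the medians were 0.04 and -0.187 for ribosomal proteins, and -0.666 and -0.004 for mitochondrially encoded genes. The heat shock, NF-kappaB, cholesterol, redox enzyme, proteasome and respiratory chain lists ranked higher under menadione, and the aminoacyl-tRNA synthetase and autophagy lists lower. Their adjusted p ran from 1.44e-06 to 0.0244, against an adjusted p = 0.337 to 0.878 with an estimated correlation. In all 644 genes differed, 429 higher and 215 lower under menadione. The count was 3285 (2001 higher, 1284 lower) with the replicate block and 1397 by DESeq2, but 5 with effective lengths as an offset, 11 by limma on log2(TPM + 1) and 1 with the 4 libraries fitted alone. It was 42 without menadione replicate 1, 438 without menadione replicate 2, 704 without TBOOH replicate 1 and 49 without TBOOH replicate 2.

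At 1 h hypoxia targets had a median of -0.49 in menadione against TBOOH (-0.217 and -0.731 within replicates 1 and 2). Of the 20, 7 were lower under menadione when adjusted over the list alone and 0 over all genes, with 9 at an unadjusted p under 0.05, 2 by DESeq2 and 1 with the block. The list ranked lower by camera at an adjusted p = 2.98e-24, and at an adjusted p = 0.0398 with an estimated correlation. The latter call was lost at an adjusted p = 0.155 with both the block and an estimated correlation. Immediate early, heat shock and ribosomal protein lists ranked higher under menadione and metal response genes lower, at adjusted p from 2.21e-11 to 0.0125, against an adjusted p = 0.28 to 0.914 with an estimated correlation. Over all genes edgeR called 0, with 384 at an unadjusted p under 0.05 and 14 by DESeq2. With the replicate block 19 passed (5 higher, 14 lower), and proteasome and respiratory chain lists ranked higher (adjusted p = 0.142 and 0.142 without, 0.015 and 0.00533 with it). Both list calls were lost at an adjusted p = 0.954 with both the block and an estimated correlation. The count was 1 without menadione replicate 1, 3 without TBOOH replicate 1 and 0 without each of the other 2 libraries.

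Shared changes of the oxidants were counted against the same vehicle libraries. At 8 h, 70 genes rose under both (5.8 by chance) and 11 fell under both (0.91 by chance), and at 24 h 44 rose (3.32 by chance) and 22 fell (2.39 by chance). Genes such as HMOX1 and SLC7A11 rose under both at 8 h. Over all 17834 genes, which are not independent replicates, the fold changes under menadione and TBOOH correlated at r = 0.502 at 1 h, 0.554 at 8 h and 0.592 at 24 h. Simulated libraries with no treatment effect and the same shared vehicle gave a mean r of 0.506, 0.496 and 0.501. The r at 1 h lay within the range of the simulations (0.461 to 0.54) and those at 8 and 24 h above the highest of them (0.538 and 0.552). In these simulations the shared controls alone gave an r not far below those at 8 and 24 h, so much of that r can come from them. Part of the excess overlap may come from the shared controls too. With TBOOH set against earlier control libraries, so that none was shared, r was 0.027, 0.243 and 0.22. With each oxidant taken from the other replicate number, against the vehicle library of its own number, r was -0.015 and -0.023 at 1 h, 0.34 and 0.173 at 8 h, and 0.185 and 0.241 at 24 h (menadione from replicate 1, then from replicate 2). The covariance, 0.157, 0.285 and 0.317, exceeded the simulated means by 0.0455, 0.181 and 0.212. At 1 h it also exceeded the highest simulated value, 0.121, though r without shared libraries was 0.027, -0.015 and -0.023. The simulated covariance may thus be too low, and the excesses at 8 and 24 h may overstate a shared effect. Within replicate 1 alone r was 0.537, 0.541 and 0.533, and within replicate 2 alone 0.509, 0.533 and 0.614. It ran from 0.285 to 0.777 at 1 h, 0.382 to 0.734 at 8 h and 0.382 to 0.776 at 24 h when single libraries were left out.

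The change of each response between times asked which genes responded differently early and late. The menadione response rose from 1 to 8 h for ALDH3A1 by 4.0 ± 0.28, AKR1C3 by 2.47 ± 0.31, CYP4F11, a fatty acid hydroxylase, by 2.31 ± 0.34 and AKR1C2 by 2.27 ± 0.36, with adjusted p from 4.81e-05 to 0.0428, among 13 genes, all with a rising response. The TBOOH response rose over that time for ASNS by 2.36 ± 0.29, SLC7A5 by 2.02 ± 0.26, PCK2 by 1.72 ± 0.16 and MTHFD2, of mitochondrial folate metabolism, by 1.60 ± 0.24, and fell for the chaperone HSPA2 at -2.04 ± 0.29, among 8 genes (7 rising, 1 falling). From 8 to 24 h the TBOOH response fell for MT1X at -4.05 ± 0.56, the amino acid transporter SLC1A4 at -1.56 ± 0.20 and CALR at -1.04 ± 0.11, the 3 genes past the test. For menadione from 8 to 24 h edgeR called 0, with 462 at an unadjusted p under 0.05, 5 by DESeq2 and 7 with the replicate block. With the replicate block the other counts were 79, 794 and 738 in the order given, and 0 with effective lengths as an offset, where edgeR gave 291, 607 and 442 genes at an unadjusted p under 0.05 and DESeq2 without it 54, 317 and 261. Without single libraries the menadione count from 1 to 8 h was 3 and 1 (vehicle at 1 h, replicates 1 and 2), 1 and 4 (menadione at 1 h) and 1 each at 8 h, and the TBOOH count 1 and 4 (vehicle at 1 h), 8 and 1 (TBOOH at 1 h), 5 and 1 (vehicle at 8 h) and 941 and 1 (TBOOH at 8 h). The TBOOH count from 8 to 24 h was 0 without either vehicle library at 8 h, 305 and 1 without TBOOH replicates 1 and 2 at 8 h, 1 without either vehicle library at 24 h, and 2 and 1 without TBOOH replicates 1 and 2 at 24 h. The menadione count from 8 to 24 h was 1 without menadione replicate 1 at 24 h and 0 without each other library.

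Vehicle libraries were compared over time, and with untreated cells at 0 h, for the background of the culture. Between 0 and 1 h, ethanol, any change of medium and time in culture cannot be told apart. ALDH1A3, an aldehyde dehydrogenase, rose by 1.55 ± 0.16 from 1 to 8 h (adjusted p = 0.00392) and the RNA-binding protein RBM24 fell by 1.25 ± 0.17 (adjusted p = 0.0426). The count of 2 was 131 (61 higher, 70 lower) with the replicate block and 71 by DESeq2, but 0 with effective lengths as an offset, by limma on log2(TPM + 1) and with the 4 libraries fitted alone, which gave 308, 296 and 764 at an unadjusted p under 0.05. The count was 0 and 1 without vehicle replicates 1 and 2 at 1 h, and 2 and 0 without those at 8 h. Between untreated cells at 0 h and vehicle at 1 h edgeR called 0 genes, with 527 at an unadjusted p under 0.05, 28 by DESeq2 and 27 (25 higher, 2 lower) with the replicate block. Among the latter, named after their values were seen, were the chemokine CXCL8 at 3.26 ± 0.50, the NF-kappaB inhibitors TNFAIP3 at 2.04 ± 0.29 and NFKBIA at 1.14 ± 0.13, and the transcription factor SRF at 0.85 ± 0.12. Between 8 and 24 h of vehicle edgeR called 0 genes, with 449 at an unadjusted p under 0.05, 2 by DESeq2 and 0 with the replicate block.

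**Figure D5:**
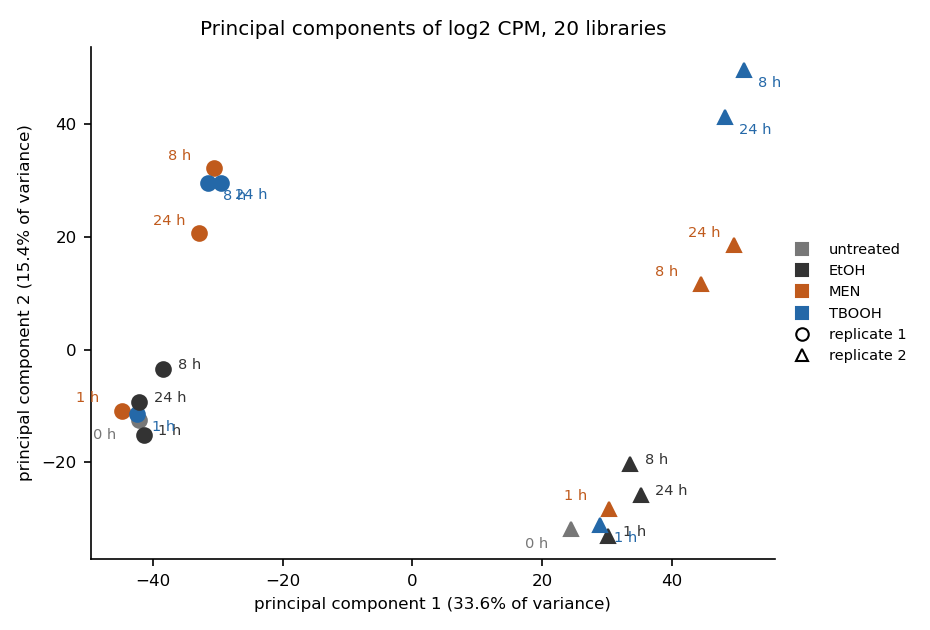
First and second principal components of log2 CPM for the 20 libraries, with treatment as colour and replicate number as shape. The first, with 33.6% of the variance, separated the 10 libraries of replicate 1 from the 10 of replicate 2, and the second held 15.4%.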

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

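All tests of explanations here were chosen after the results were seen, while the tests of the change of response between times were planned.

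The menadione response differed between 1 and 8 h for 13 genes by the interaction of treatment and time, and 4 of them fell under the rule for named genes. ALDH3A1 changed its response by 4.0 (log2), AKR1C3 by 2.47, CYP4F11 by 2.31 and AKR1C2 by 2.27. The TBOOH response differed between 1 and 8 h for 8 genes, with ASNS at 2.36, SLC7A5 at 2.02, PCK2 at 1.72, MTHFD2 at 1.60 and HSPA2 at -2.04. Between 8 and 24 h the TBOOH response differed for 3 genes, MT1X at -4.05, SLC1A4 at -1.56 and CALR at -1.04. The menadione count was 3 and 1 without vehicle replicates 1 and 2 at 1 h, 1 and 4 without those of menadione at 1 h, and 1 without each of the 4 libraries at 8 h. The TBOOH count from 1 to 8 h was 1 and 4 without vehicle replicates 1 and 2 at 1 h, 8 and 1 without those of TBOOH at 1 h, 5 and 1 without those of vehicle at 8 h and 941 and 1 without those of TBOOH at 8 h. From 8 to 24 h it was 0 without either vehicle library at 8 h, 305 and 1 without TBOOH replicates 1 and 2 at 8 h, 1 without either vehicle library at 24 h, and 2 and 1 without TBOOH replicates 1 and 2 at 24 h.

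Genes of the aryl hydrocarbon receptor rose under menadione. A list of its targets was made after CYP1A1 and CYP1B1 had been seen. Of its 7 tested genes, 7 were higher at 8 h and 7 at 24 h. Under TBOOH 1 and 2 were higher (4 and 6 with the replicate block). The list medians at 8 and 24 h were 2.14 and 2.72 under menadione, and 0.65 and 0.7 under TBOOH. Reads moved between paralogs are argued against, since the summed CYP1 and ALDH3 counts were higher in each same-numbered pair, by 0.93 (log2) at the least, and a single library is argued against by a lowest list median of 2.01. In each of 4 same-numbered pairs, the median of all 7 genes differed between menadione and TBOOH by more than the NRF2 median did. The excess was 1.17 (log2) at the least. CYP1A1 and CYP1B1, seen before the list was made, were among the largest differences between the oxidants. The excess thus cannot decide whether an NRF2 response common to both oxidants was the whole cause, which stays open. Summed counts of the UGT1A genes stood above vehicle by 1.85 and 1.98 (log2, replicates 1 and 2) under TBOOH at 24 h. A candidate explanation, as a hypothesis, is that menadione or a product of it activates this receptor, which these data do not test.

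The replicate number separated the libraries. Depth is argued against, since all 12 libraries with totals in the range of the other number stayed on their own side of the first component. With effective lengths as an offset the biological coefficient of variation rose from 0.235 to 0.416, so this correction did not remove the split. It rose with the replicate block too, from 0.085 to 0.128, and the effective lengths themselves differed by replicate number. The test thus cannot decide whether a bias as Salmon modelled it was the cause. Gene length as the whole cause is argued against. After removal of a smooth trend with length, replicate differences still correlated at 0.467 to 0.604 over the 45 pairs of groups. Before it they correlated at 0.468 to 0.606. A length trend was present, with a Spearman rho of -0.221 over genes before and -0.057 after. A difference in library preparation or sequencing run stays open and untested, as does a separate culture for each number, and GC content was not tested for want of the genome sequence.

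Fold changes under TBOOH at 8 h were wider in replicate 2. The spread of the 30 list medians in replicate 2 was 1.58 times that in replicate 1, against 0.8 and 1.24 for menadione at 8 and 24 h, which argues against wider changes in all replicate 2 libraries, while TBOOH at 1 and 24 h gave 2.01 and 1.6. Mitochondrial rRNA taking counts would shift all lists to 1 side, and TMM scaling removes such a common shift. A common shift could thus not have been seen in these medians. The mitosis median shifted by -0.46 and the ATF4 median by 0.85, which a common shift alone would not give. Replicate 2 libraries of TBOOH at 1 and 24 h, where the spread was wider too, held 1.88 and 1.94% mitochondrial rRNA. A defect of the 8 h library alone thus cannot account for the wider spread at those times. At 8 h, RNA quality in the TBOOH replicate 2 library, with 3.76% of counts from mitochondrial rRNA, cannot be told apart from a stronger response. The share was not raised in that library alone, since TBOOH replicate 1 at 8 h held 2.45% against 1.49% in its vehicle. No measure of RNA integrity was analysed here. A higher effective dose in the cells of that library stays open and untested, and nothing states that they were a separate culture.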

How the results depend on the processing

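The fits with both the replicate block and effective lengths, the block with 1 library left out or an estimated correlation, and the correlations within or across replicate numbers were chosen after the data were seen, and the other alternatives were planned.

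The direction of all 267 called changes of named genes was kept under each alternative that tested the gene, and calls were what moved. In comparisons of 2 groups, the rule for named genes asked for both libraries of a group above both of the other. A kept direction was thus largely set by that choice. The replicate block and DESeq2 kept all 267 calls, RLE scaling 262, total count scaling 248 and robust dispersion 266, the stricter filter all 246 it tested, and no filter 244. Effective lengths as an offset kept 29, limma on log2(TPM + 1) 39 and a fit of the compared groups alone 13, while both block and offset kept 253. Without 1 library 517 of 1116 calls were kept, and 1009 with the replicate block. Leaving out a library unbalances the replicate numbers, and a fit of 4 libraries alone has fewer degrees of freedom by construction. The offset kept 29 calls without the block and 253 with it. Its loss of calls thus went largely with the replicate split being left out of the fit. For all other moved values the cause was not tested. Against vehicle, the block ended 2 list calls of camera with its preset correlation and added 7, and it ended all 5 that passed with an estimated correlation. Depth limits genes of low count, which the filter removed only in part. Of the 17834 genes tested, 12744 had a mean log2 CPM of at least 1.

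Counts below run over menadione at 1, 8 and 24 h, TBOOH at 1, 8 and 24 h, and menadione against TBOOH at 1, 8 and 24 h, then vehicle at 1 h against 0 h, 8 h against 1 h and 24 h against 8 h, and the menadione and TBOOH responses from 1 to 8 h and 8 to 24 h. They were 0, 172, 165, 1, 1494, 1380, 0, 298, 644, 0, 2, 0, 13, 0, 8 and 3 as reported. With the replicate block they were 4, 1133, 1289, 22, 4698, 4628, 19, 2194, 3285, 27, 131, 0, 79, 7, 794 and 738. With both block and effective lengths they were 2, 433, 600, 10, 2572, 2319, 3, 767, 1522, 10, 34, 0, 24, 2, 117 and 64. With no filter they were 104, 635, 704, 114, 1931, 1793, 120, 807, 1065, 171, 234, 120, 207, 140, 601 and 313. By DESeq2 they were 7, 490, 474, 23, 2137, 2038, 14, 870, 1397, 28, 71, 2, 54, 5, 317 and 261.

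With effective lengths alone, menadione at 8 and 24 h gave 11 and 24, TBOOH 0, 15 and 6, the oxidants against each other at 8 and 24 h 0 and 5, vehicle from 1 to 8 h 0, and the 3 changes of response with calls 0 each. By limma on log2(TPM + 1) these were 17 and 36, 0, 31 and 18, 16 and 11, 0, and 0, 2 and 1. With the compared groups alone they were 15 and 2, 0, 0 and 0, 0 and 1, 0, and 7, 0 and 0. The stricter filter gave 2 for TBOOH at 1 h, 47 for its response from 1 to 8 h and 6 from 8 to 24 h. Total count scaling gave 1 for vehicle from 1 to 8 h and 21 for the menadione response from 1 to 8 h, and robust dispersion 15 for that of TBOOH. RLE scaling moved no count beyond 1.5 times.

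Without single libraries, with and without the replicate block, counts ran from 0 to 5 for menadione at 1 h, 21 to 713 at 8 h and 30 to 666 at 24 h, and for TBOOH 0 to 25, 10 to 5899 and 25 to 4383. The oxidants against each other gave 0 to 19, 33 to 3678 and 42 to 2905. Vehicle gave 0 to 13, 0 to 18 and 0 to 3, and the changes of response 1 to 80 and 0 to 15 (menadione) and 1 to 3737 and 0 to 2269 (TBOOH).

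The correlation of the oxidants, 0.502, 0.554 and 0.592 at 1, 8 and 24 h, was 0.729 at 1 h and 0.576 at 8 h with the stricter filter, 0.512 at 8 h and 0.534 at 24 h with no filter, and 0.547 at 8 h with effective lengths. Within replicate 1 it was 0.537, 0.541 and 0.533 and within replicate 2 0.533 at 8 h. With TBOOH set against earlier control libraries, so that no library was shared, it was 0.027 at 1 h (untreated cells), 0.243 at 8 h (vehicle at 1 h) and 0.22 at 24 h (vehicle at 8 h). With each oxidant from the other replicate number, which also shares no library, it reversed at 1 h to -0.015 and -0.023 (menadione from replicate 1, then 2) and was 0.34 and 0.173 at 8 h and 0.185 and 0.241 at 24 h. Without single libraries it ran from 0.285 to 0.777, 0.382 to 0.734 and 0.382 to 0.776. Of 180 pairs of list and comparison, 79 passed camera as reported, 5 with an estimated correlation, 36 by fry and 0 with both block and an estimated correlation.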

Other observations

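The share of counts on transcripts annotated as retained introns, measured after the data were seen and not tested, differed from vehicle of the same replicate number by 0.40 and 0.57 percentage points (replicates 1 and 2) under TBOOH at 8 h, and by 0.31 and 0.39 at 24 h. Under menadione the differences were 0.32 and 0.24 at 8 h and -0.17 and 0.35 at 24 h. At 1 h they were 0.28 and 0.36 under menadione and 0.04 and 0.15 under TBOOH. The share itself was 4.38 to 4.86% in replicate 1 libraries and 5.17 to 5.90% in replicate 2 libraries.

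The metallothionein MT1X returned toward vehicle after 8 h of TBOOH. HMOX1 stood at 254 ± 263 CPM at 8 h and 39.8 ± 30.6 CPM at 24 h, and MT1X at 106 ± 27.7 and 5.23 ± 0.368 CPM, with the difference between times past the test for MT1X alone of the pair (HMOX1 adjusted p = 0.577). FTH1, the ferritin heavy chain, was at 1.41 ± 0.52 under menadione and 1.52 ± 0.52 under TBOOH at 24 h, past the test with the replicate block (adjusted p = 0.000157 and 0.000132) and not without it (adjusted p = 0.289 and 0.0949).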
